A study of Mus musculus with 4 samples.

How the data were processed

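Ribosome-bound RNA was sequenced from 4 libraries of olfactory epithelium, 2 of the open and 2 of the closed side. Per the labels' protocols, epithelia were dissected and divided, tagged ribosomes were precipitated, ribosomal RNA was depleted, and libraries were made with the NuGEN Ovation V2 amplification kit and sequenced as paired reads of 150 bases. The submitters' processing notes name Trim Galore, Trimmomatic, HISAT2, featureCounts, DESeq2 and the mm10 build, without versions, roles or order, and no setting for strand or for reads that match several transcripts.

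The deposited table gives log2 values per transcript and library, and the authors' ratio of open over closed. The steps between low values show a variance-stabilizing transformation of reads divided by 1 size factor per library, with 0 reads written as 3.547. The authors' deposited averages are the mean of 2 to the power of these log2 values, a signal on a linear scale that includes the floor, and the deposited ratio divides the averages. In the authors' deposited table this ratio was at least 2 for 8664 and at most 0.5 for 7336 of 142446 transcripts. The scale compresses differences of low transcripts, so a log2 difference understates the fold change of a gene with few reads.

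The transformation was inverted by fitting its floor and size factors to the lowest 30 steps of each library. Size factors were 1.99 and 1.23 for open replicates 1 and 2, and 0.322 and 1.38 for closed replicates 1 and 2. All low values checked (100%) came out as whole reads within 0.1 reads. These reads gave the depth of each library, from 10666429 to 36487356 over genes, and 1 read was worth 0.503 to 3.11 normalized counts. Intervals and floors from them cover counting error only, since amplified reads are not independent molecules. The depth stated in the labels counts sequenced fragments, which is not the same quantity.

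Of 143181 rows, 287 without a gene name were left out of tests and totals. They include the ribosomal RNA transcript that took 7.66% to 60.1% of reads. Each of 55384 genes was represented by its transcript row with the highest mean, because rows of 1 gene share reads and their sum would count reads repeatedly. Transcripts were matched to GENCODE vM21, which is on the same build (99.1% found), and coordinates are those of the gene there. Genes with a mean of at least 10 normalized counts were tested, 20968 in all, among them 673 of 1104 odorant receptor genes. Receptor pseudogenes, 306 in all, were left out of the receptor list.

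Groups were taken from the side label. The titles of both open libraries read as closed with the right side, while their side label and column names read open. Replicate 1 is male and replicate 2 female on both sides. The number of animals behind a library is not stated, so p-values refer to these samples only. The p-values and SEs are moderated by limma, which combines a gene's own spread with a prior variance drawn from all tested genes. In the main test the own spread had 2 degrees of freedom and the prior 14.6. That prior was 45.4 with library quality weights and 91.5 with limma-voom. In fits with an infinite prior, such as those with the block, p-values rest on a variance shared between genes instead. Libraries with the same number were treated as pairs, since epithelia were divided into sides and the same number shares its sex, although the labels do not say outright that both came from the same animals. The check of this pairing gave a correlation of 0.0886 between the deviations of same-numbered libraries from their side means over 20968 genes, and 0.133 over the 15474 genes with a mean of at least 50. Both groups have 2 libraries, so other splits of the libraries were not counted.

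The test was limma-trend (limma 3.58.1, R 4.3.3) on the deposited log2 values with side as the only term, two-sided, with Benjamini-Hochberg adjustment and log2 differences given as open minus closed. The planned scale was log2 of a normalized count plus 1 with rows summed to genes. The deposited values were already on a log scale, so they were used as they stand and the planned scale became an alternative. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 35 lists with at least 3 tested members. The 34 lists of 482 genes, the receptor list, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. The spread of receptor differences was compared with 10000 random lists drawn from 20 bins of mean expression, and the agreement of pairs with 1000 such lists. Values came from Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

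The rule named the 10 genes per direction with the largest difference among those past adjusted p 0.05 with the same sign in both pairs. Since none passed, it took those with the lowest unadjusted p among genes with the same sign in both pairs and a mean of at least 50. It added the 10 receptor genes with the lowest p, the 4 members with the lowest p of each list, receptor genes known from earlier work, and Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Rpl22 and Ascl1. This gave 173 genes, of which the text names those that describe each group.

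Alternatives were pseudocounts of 0.5 and 5 on back-transformed counts, no filter and a mean of at least 50, rescaling by trimmed means and by the median ratio of genes other than receptors, limma without trend, each transcript row by itself, the replicate block, and each library left out. The planned pseudocount of 1 and the planned sum of rows were each run as an alternative once the deposited scale was known. Added after the data were seen were library quality weights, limma-voom on the recovered reads with and without the block, thinned reads and each pair alone. On simulated reads of 20968 genes with a dispersion of 0.0999, the test of open against closed recovered 6% of 50 genes changed by a fold of 2, 66% at 4, and 100% at 8 and at 16, with 0 false calls. With the block it recovered 8%, 82%, 100% and 100%, with 6 false calls. The changed genes were drawn only from those with a mean of at least 50 normalized counts, so recovery below that mean was not simulated. Of the 673 tested receptor genes, 279 reach that mean. The dispersion was the median over genes in the open libraries alone and was given to all simulated libraries. The closed libraries varied more, with quality weights of 0.587 against 1.70 for the open ones. Recovery in these data may therefore be lower than in the simulation.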

Results

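Ribosome-bound RNA of newly generated olfactory sensory neurons was measured on the open and the closed side of the mouse olfactory epithelium after 1 naris had been sealed. Naris occlusion cuts the flow of odorants to the sealed side, so the comparison asks how a lack of odour stimulation alters transcripts of neurons born after the closure. The mice carried a tamoxifen-dependent Cre recombinase under control of Ascl1, a gene of neuronal progenitors, and a ribosomal protein Rpl22 allele that gains an HA tag after recombination. The naris was closed on postnatal day 14, tamoxifen was given on days 28 and 29, and tissue was taken on day 35. Tagged ribosomes were precipitated with an antibody against HA, and their RNA was sequenced. Each side had 2 libraries, replicate 1 from male and replicate 2 from female mice. The closed side was always the left one, so side and occlusion cannot be separated.

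The libraries differed in depth and in ribosomal RNA. Reads over genes came to 36487356 and 28209356 in open replicates 1 and 2, and to 10666429 and 32604902 in closed replicates 1 and 2. A ribosomal RNA transcript on chromosome 17 (39846353 to 39848827, mm10) took 60.1% of the reads of closed replicate 1, against 7.66%, 11.1% and 9.38% in open replicate 1, open replicate 2 and closed replicate 2. Of 20968 tested genes, 2298 had no read in closed replicate 1, against 166, 251 and 109 in the other libraries.

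**Figure D1:**
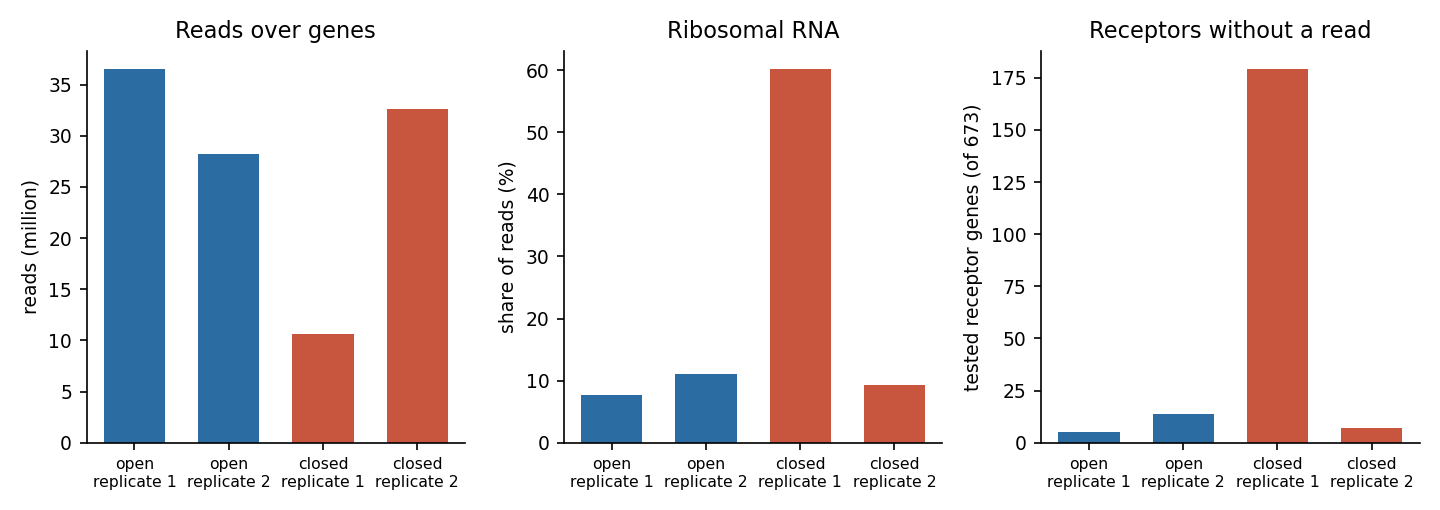
Bars give, for each of the 4 libraries (open in blue, closed in red), the reads over genes, the percentage of reads on the ribosomal RNA transcript, and the number of the 673 tested odorant receptor genes without a read. Closed replicate 1 stands apart with 10666429 reads, 60.1% ribosomal RNA and 179 receptor genes without a read.

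Sex-linked transcripts matched the labels. Xist, the RNA that coats the inactive X chromosome, stood at log2 values of 4.43 and 4.28 in the male open and closed libraries and at 9.83 and 9.08 in the female ones. The Y-linked gene Ddx3y stood at 9.63 and 10.36 in the male libraries and at 3.93 and 4.34 in the female ones. Eif2s3y, Kdm5d and Uty, also on the Y chromosome, were likewise higher in both male libraries. Rpl22, the gene that carries the tag, differed by -0.01 ± 0.55 between sides (log2 open minus closed ± moderated SE, n = 2 per side), and Ascl1 by 0.62 ± 0.74. Each SE given with a log2 difference is moderated in this way and draws on other genes, so it does not show a gene's own spread.

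Bpifb9a and Bpifb9b, neighbouring paralogs on chromosome 2 (154257854 to 154271245 and 154307227 to 154320646) that encode secreted BPI-fold proteins, were lower on the open side by log2 differences of -5.62 ± 1.01 and -5.54 ± 1.02 (SE, n = 2 per side). Their differences were -3.73 and -3.62 in the replicate 1 pair and -7.52 and -7.45 in the replicate 2 pair. Bpifb9a stood at log2 values of 9.69 and 10.65 in open replicates 1 and 2, and at 13.42 and 18.17 in closed replicates 1 and 2. Closed replicate 2 is the library with intestine-type transcripts described below. Bpifb9b was also on the preset list of genes of Bowman's glands and secretory cells. Whether this RNA came from labelled neurons was not tested. 5430401F13Rik on chromosome 6 (131486400 to 131553763) differed by -3.14 ± 0.54, with -3.11 and -3.18 in the pairs. Il23a, a subunit gene of the cytokine interleukin 23, differed by -3.86 and -2.14 in the pairs, Dnase1 by -3.02 ± 0.67 over all libraries, and the calcium-dependent membrane-binding protein gene Anxa4 by -3.25 ± 0.86, with -5.45 and -1.06 in the pairs and -1.41 without closed replicate 1. Pigr, the receptor that carries polymeric immunoglobulins across secretory epithelia, differed by -2.17 ± 0.57.

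On the open side, S100a5, a calcium-binding protein gene of olfactory neurons whose expression is known to follow odour stimulation, was higher by 2.28 ± 0.76 (SE, n = 2 per side). S100a5 (chromosome 3, 90608523 to 90611780) differed by 2.18 in the replicate 1 pair and by 2.38 in the replicate 2 pair. With 1 library left out S100a5 ranged from 1.13 to 3.43, and its log2 value in open replicate 2 (10.86) was close to that in closed replicate 1 (10.79). Gm43795 differed by 3.08 ± 0.94, with 2.39 and 3.76 in the pairs and 2.03 to 4.13 with 1 library left out. The other 8 genes that the rule named as higher were Tmem150c, 2610005L07Rik, Gm48952, Nrbp2, Dlg2, Zbed5, Abhd12 and Gm15850. Each of these lay further from 0 in the replicate 1 pair, for example Dlg2 with 4.18 against 0.95 and Abhd12 with 4.42 against 0.36. Their normalized counts in closed replicate 1 ran from 0 (Gm15850) to 128 (Tmem150c). In closed replicate 2 they ran from 110 (Dlg2) to 688 (Nrbp2). Without closed replicate 1 these 8 differences lay between 0.75 (Gm48952) and 1.33 (Dlg2).

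None of these genes passed adjusted p 0.05 in the test of side alone. limma-trend put 0 of 20968 genes past the threshold, with a smallest adjusted p of 0.263. At an unadjusted p under 0.05 were 362 genes, 127 of them higher and 235 lower on the open side. Their share is smaller than the 0.05 that would be met without any difference. With the replicate number as a block, 18 genes passed, 2 higher and 16 lower. That fit had 1 residual degree of freedom and an infinite prior, so its p-values rest on a variance shared between genes. A gene's own spread between the 2 pairs carries no weight in them, as for Bpifb9a with a blocked SE of 0.60. The blocked adjusted p in limma was 1.43e-16 for Bpifb9a, 1.19e-15 for Bpifb9b, 1.62e-05 for 5430401F13Rik, 2.08e-05 for Anxa4, 6.83e-05 for Il23a, 0.0184 for Dnase1, 0.0145 for Pecam1 and 0.0181 for S100a5, while Pigr had 0.082. Over 18 other settings the limma adjusted p of S100a5 ran from 0.00644 to 1 and passed in 4, and that of Bpifb9a ran from 5.27e-20 to 0.995 and passed in 9. Also past the threshold with the block were Gm6619, mt-Tv and mt-Nd2, and, named here after their values were seen, Bpifb5, Cabs1, Gm37612, Gm42413, Gm14336, Gm42553 and Gm17814. Several of the 18 rested on the replicate 1 pair: Pecam1 differed by -4.58 and -0.06 in the pairs, Gm17814 by -4.28 and -0.09, Gm42413 by 5.82 and 0.14, Gm37612 by -6.29 and -0.18 and Gm42553 by -8.24 and 0.33. Cabs1 rested on the replicate 2 pair, with -0.47 and -7.75. limma-voom on recovered reads put 9 genes past the threshold without the block and 39 with it, and 17 of the 18 were among the 39. The limma-voom fit with the block also had an infinite prior, so it shares that limit.

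Exons overlap in part between 5430401F13Rik and Gm6619, Gm48952 and Nrbp2, Tmem150c and Tmem150cos, Dnase1 and Trap1, Anxa4 and Gm44036, Gm42413 and Qdpr, mt-Nd2 and mt-Tw, mt-Atp8 and mt-Atp6, and mt-Nd5 and mt-Nd6, and how reads in the shared parts were assigned is not stated. Leaving out closed replicate 2 gave 265 genes past adjusted p 0.05 (154 higher and 111 lower on the open side), and leaving out open replicate 1, open replicate 2 or closed replicate 1 gave 2, 10 and 5, each fit with a lone library on 1 side assumed to vary like the others and with the sexes unevenly shared between sides.

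**Figure D2:**
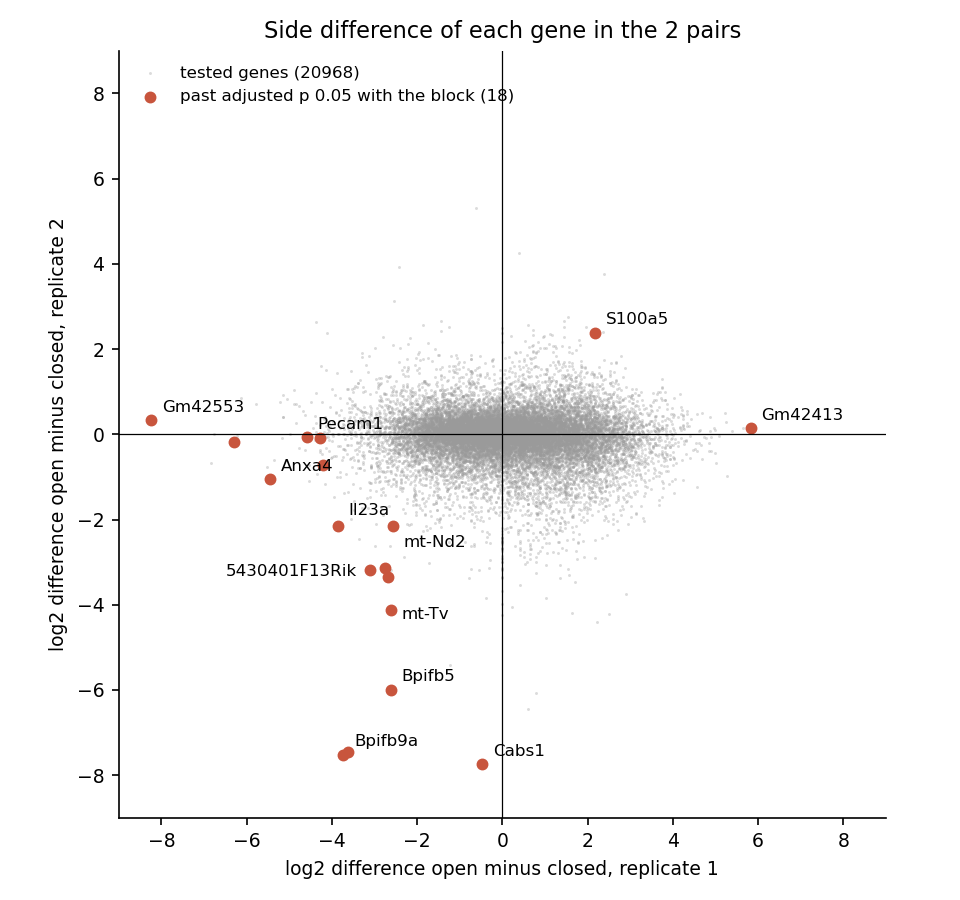
Each point is 1 of 20968 tested genes, with the log2 difference open minus closed in the replicate 1 pair on the x axis and in the replicate 2 pair on the y axis; red points are the 18 genes past adjusted p 0.05 with the replicate block. S100a5 lies at 2.18 and 2.38, Bpifb9a at -3.73 and -7.52, and across all tested genes the pairs had a Pearson r of -0.0478.

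Protein-coding transcripts of the mitochondrial genome were lower on the open side. All 13 were lower in both pairs, with a median log2 difference of -1.35, medians of -1.48 and -1.51 in the pairs, and the largest single difference at mt-Atp8 with -2.60 ± 0.71 (SE, n = 2 per side). mt-Nd2, a subunit of respiratory complex I, differed by -2.36 ± 0.55, mt-Nd5 by -1.92 ± 0.56 and mt-Atp6, a subunit of ATP synthase, by -1.68 ± 0.56. The list passed camera with a preset correlation (adjusted p = 1.31e-12) and did not with an estimated correlation (adjusted p = 0.532 with an estimated correlation). None of the 13 passed over all genes, 8 passed adjusted over the list alone in limma, and mt-Nd2 had a blocked adjusted p of 0.0135. Mitochondrial ribosomal RNA took 0.624% and 0.891% of gene reads in open replicates 1 and 2, and 14.4% and 1.32% in closed replicates 1 and 2. The 17 nuclear genes of oxidative phosphorylation had a median of -0.04, with 4 members higher and 5 lower in both pairs. Their pair medians were 0.18 and -0.04, and over 13 other settings the median ran from -0.19 to 0.39.

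**Figure D3:**
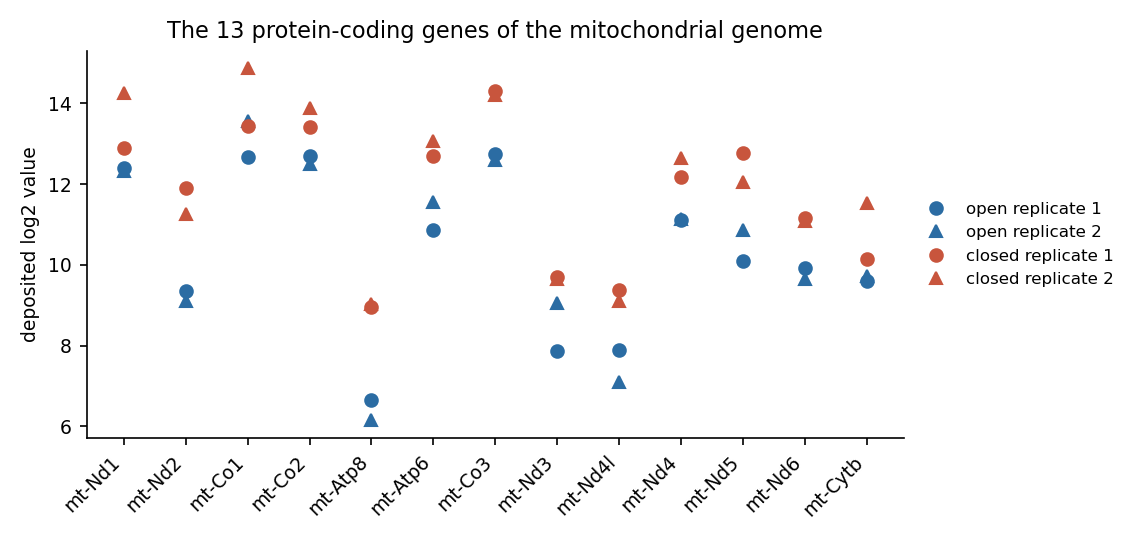
Points give the deposited log2 value of each of the 13 mitochondrial protein-coding genes in each library (blue open, red closed, circles replicate 1, triangles replicate 2). In each pair of like symbols the closed library lies above the open one for all 13 genes, with median differences of -1.48 and -1.51 open minus closed.

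Genes known to follow odour-driven activity were examined as a preset list. Of its 13 tested members, 7 were higher on the open side in both pairs and 1 was lower in both, with a median log2 difference of 0.32. The pair medians were 0.05 and 0.51, and over 13 other settings the median ran from 0.12 to 0.41. Besides S100a5, the members with the lowest p were Pcp4l1, a relative of the calmodulin regulator gene Pcp4, with 1.55 ± 0.59 (2.32 and 0.79 in the pairs, 0.86 to 2.25 with 1 library left out), Lrrc3b with 1.74 ± 1.02 and the adhesion molecule gene Kirrel2 with 0.77 ± 0.54 (SE, n = 2 per side). The list did not pass camera (adjusted p = 0.623) and passed without closed replicate 1 (adjusted p = 8.19e-04, median 0.41, against 0.51 in the replicate 2 pair), where Lrrc3b stood at 0.26. Of 4 genes known to be higher with low activity, the ephrin gene Efna5, the Eph receptor gene Epha7 and the adhesion molecule gene Kirrel3 were lower on the open side in both pairs (-1.09, -0.31 and -0.15), with none past the threshold, and Efna5 stood at -0.69 without closed replicate 1. Over 18 other settings Epha7 ran from -0.63 to 0.02 and Kirrel3 from -1.39 to -0.04. The histone gene H2bc21 differed by 0.83, with 1.60 and 0.07 in the pairs and 0.12 without closed replicate 1. Of 18 immediate early genes, 6 were lower and 2 higher on the open side in both pairs, with a median of -0.56. The pair medians were -0.09 and -0.51, and over 13 other settings the median ran from -0.71 to -0.06. Nr4a1 differed by -1.66 ± 0.66, Klf2 by -1.56 ± 0.65, Egr3 by -1.74 ± 1.02 and Nr4a2 by -1.26 ± 0.82. Some of these rested on closed replicate 1: without it Egr3, which differed by 0.15 in the replicate 2 pair, stood at 0.04, Nr4a2 at -0.25 and Klf2 at -0.92, while Nr4a1 stood at -1.48. That list did not pass camera (adjusted p = 0.175) and passed without closed replicate 1 (adjusted p = 0.00232, median -0.71, against -0.51 in the replicate 2 pair).

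The 22 genes of immature neurons had a median of 0.22, with 11 higher and 1 lower on the open side in both pairs, among them the cytoskeletal regulator genes Crmp1 with 1.51 ± 0.65 and Stmn4 with 0.87 ± 0.58 (SE, n = 2 per side). Crmp1 differed by 2.71 and 0.30 in the pairs, and without closed replicate 1 it stood at 0.44 and the list median at -0.12, while Stmn4 ranged from 0.39 to 1.35 with 1 library left out. The 21 genes of mature neurons had a median of 0.13, with 7 higher and 4 lower in both pairs, such as Pde1c, a phosphodiesterase gene of olfactory cilia, with 0.66 ± 0.57 (0.25 to 1.07 with 1 library left out). Gnal, the G protein subunit gene of odour transduction, differed by 1.58 in the replicate 1 pair and by -0.13 in the replicate 2 pair. Their camera adjusted p values were 0.838 and 0.975, but the immature list passed without open replicate 1 (adjusted p = 0.0499, median 0.57) and the mature list without closed replicate 1 (adjusted p = 0.0444, median 0.23), and with 1 library left out their medians ranged from -0.23 to 0.57 and from -0.24 to 0.23. The 15 progenitor genes and 21 proliferation genes had medians of 0.13 and -0.06, with adjusted p = 0.998 each, and with 1 library left out these ranged from -0.44 to 0.58 and from -0.61 to 0.35, with proliferation past camera without closed replicate 1 (adjusted p = 0.00204).

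The pairs differed in immune and secretory markers. The 9 tested genes of lymphocytes and neutrophils had a median of -0.85, with -2.06 in the replicate 1 pair and 0.58 in the replicate 2 pair, and passed camera at adjusted p = 0.0415 but not at adjusted p = 0.999 with an estimated correlation. Only 2 of the 9 were lower in both pairs: Jchain, which joins polymeric immunoglobulins, with -2.81 ± 0.97, and the leukocyte phosphatase gene Ptprc with -1.53 ± 0.71 (SE, n = 2 per side). Ptprc differed by -2.24 and -0.82 in the pairs, and over 18 other settings Jchain ranged from -4.48 to -1.46 and Ptprc from -2.24 to -0.82. The neutrophil gene S100a8 differed by -3.79 in the replicate 1 pair and by 0.58 in the replicate 2 pair. The 14 genes of Bowman's glands and secretory cells had a median of -0.37, with pair medians of 0.38 and -1.17. Of these, Bpifb9b passed adjusted over the list alone, the odorant-binding protein genes Obp1a and Obp1b differed by -1.41 ± 0.84 and -1.32 ± 0.86, and Bpifb4 differed by 0.97 ± 0.65. Without closed replicate 2 these stood at -0.10 for Obp1a, 0.23 for Obp1b and 0.32 for Bpifb4, and without closed replicate 1 at -2.72, -2.88 and 1.62. The 13 macrophage genes had pair medians of 1.12 and -0.73. Mrc1, a macrophage lectin receptor gene, differed by -4.28 and -0.36 in the pairs. Camera gave adjusted p = 0.367 for the gland list and 0.838 for the macrophage list. The gland list passed without open replicate 1 (7.76e-05, median -0.68) and without closed replicate 1 (0.00359, median -0.78), the macrophage list without closed replicate 1 (7.28e-04, median -0.85), and with 1 library left out their medians ranged up to 0.12 and 0.97.

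The 18 sustentacular cell genes had a median of 0.05, the 16 stroma genes -0.27 and the 12 endothelial genes -0.09, none past camera, and with 1 library left out they changed sign, from -0.28 to 0.10, from -0.59 to 0.09 and from -0.39 to 0.29. Of the 35 lists tested, 2 passed camera with the preset correlation and 0 with an estimated one. Without closed replicate 1 the number was 14, 3 higher and 11 lower on the open side, but that fit sets male and female open libraries against 1 female closed library, the one with intestine-type transcripts, so differences by replicate number enter it. Proliferation and interferon-stimulated genes had medians of -0.61 and -0.78 in that fit and -0.14 and -0.26 in the replicate 2 pair, and antimicrobial proteins and macrophages -1.01 and -0.85 against -1.06 and -0.73.

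**Figure D4:**
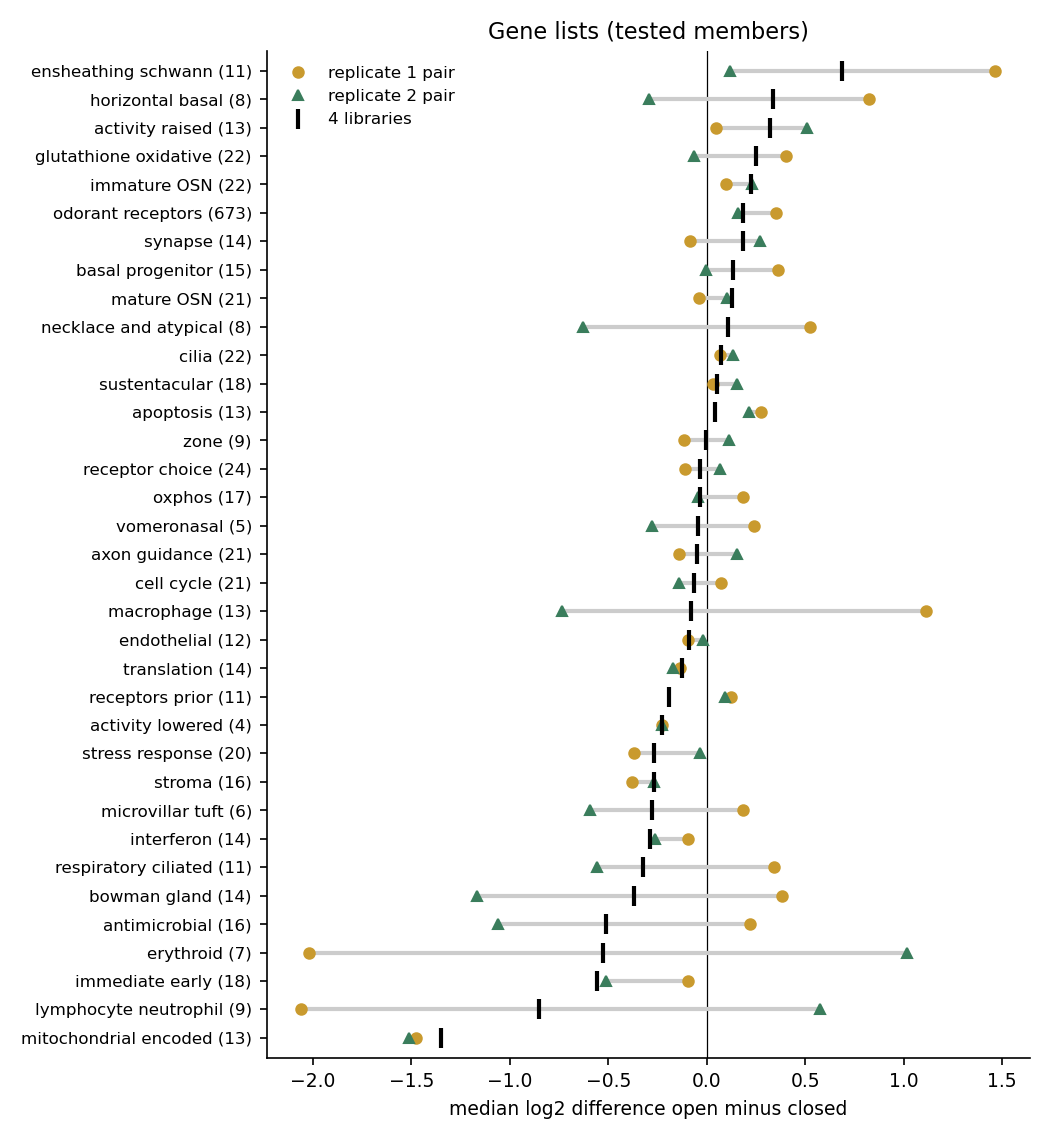
Each line is 1 of 35 gene lists with the number of tested members in brackets; the x axis is the median log2 difference open minus closed in the replicate 1 pair (circle), the replicate 2 pair (triangle) and all 4 libraries (bar). The mitochondrial list lies lowest at -1.35, with -1.48 and -1.51 in the pairs, while the pair medians of the lymphocyte list lie apart at -2.06 and 0.58.

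No odorant receptor gene passed the threshold. Of 673 tested receptor genes, each the product by which a sensory neuron detects odours, 390 were higher and 283 lower on the open side, with a median of 0.19. The 10 with the lowest p included Olfr670 with -2.64 ± 1.02, Olfr606 with -2.37 ± 0.96, Olfr132 with 2.42 ± 0.99, Olfr729 with -2.04 ± 0.87, Olfr870 with 2.22 ± 0.96 and Olfr78 with 2.12 ± 0.94 (SE, n = 2 per side). The rest of these 10 were Olfr1505, Olfr1264, Olfr554 and Olfr117. Without closed replicate 1, Olfr670 stood at -1.40, Olfr606 at -3.03, Olfr132 at 0.97, Olfr729 at -0.85 and Olfr78 at 1.49, and Olfr870 differed by 2.88 and 1.55 in the pairs. Olfr1505 had no read in either open library or in closed replicate 2, and a log2 value of 10.31 in closed replicate 1. limma-trend called 0 receptor genes over all genes and 0 adjusted over the list alone, with 11 at an unadjusted p under 0.05, 5 of them higher on the open side. The block also called 0, with 21 at an unadjusted p under 0.05, and limma-voom called 0. Both 11 and 21 are a smaller share of the 673 than the 0.05 that would be met without any difference. Without closed replicate 2 some receptor genes passed, but closed replicate 1 was then the only closed library, and 179 of the 673 had no read there. The receptor list did not pass camera (adjusted p = 0.711) and passed without open replicate 1 (adjusted p = 0.0305, median 0.37). The median ranged from -0.06 without closed replicate 1 to 0.51 without closed replicate 2, and was -0.19 among the 279 receptor genes with a mean of at least 50 normalized counts.

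The 11 receptor genes that earlier work on occlusion, musk or sex-linked odours names had a median of -0.19, with 3 higher and 0 lower on the open side in both pairs. Olfr1440 differed by -1.44 ± 0.73, Olfr1325 by 1.86 ± 0.97, Olfr827 by 1.71 ± 0.94 and Olfr1509 by -0.99 ± 0.72 (SE, n = 2 per side), with camera adjusted p = 0.998 for the list. Without closed replicate 1 they stood at -0.44, 0.34, 0.62 and -0.42, and Olfr1440 and Olfr1509 changed sign in the replicate 2 pair (0.29 and 0.06). The trace amine-associated receptor genes Taar6 and Taar7b, the only 2 tested, differed by -1.80 ± 0.98 and -1.23 ± 1.03, and by -1.06 and 0.12 without closed replicate 1.

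Receptor genes as a family spread between sides about as widely as other genes of like abundance. The SD of their log2 differences was 0.888, at percentile 69.7 of 10000 random lists matched on mean expression, whose central range ran from 0.828 to 0.923. The SD was 1.60 in the replicate 1 pair and 0.797 in the replicate 2 pair, against matched medians of 1.61 and 0.76. Across receptor genes, which are not independent replicates, the pairs had a Pearson r of -0.0222 and a Spearman rho of -0.0150, within the range of -0.115 to 0.0203 for matched genes, and 331 of 673 receptor genes (49.2%) had the same sign in both. Receptor genes took 0.253% ± 0.024 of gene reads on the open side and 0.235% ± 0.0088 on the closed side (SD, n = 2), a difference of 0.018 percentage points with an exact two-sided permutation p of 0.667, where 2 against 2 libraries allow no p under 0.333. As a share of protein-coding gene reads the difference was -0.00729 percentage points (exact permutation p = 1.0). The spread lay at percentile 99.6 without open replicate 1 and at 0.47 without open replicate 2.

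**Figure D5:**
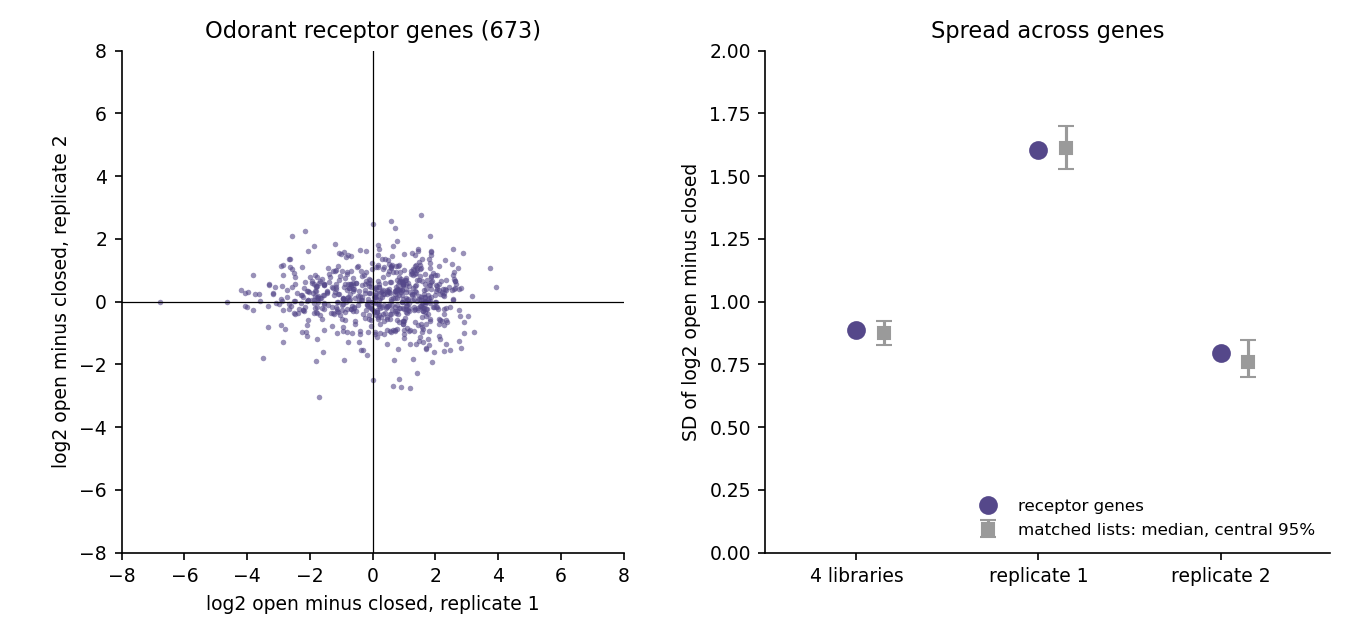
On the left, each point is 1 of 673 odorant receptor genes with its log2 difference open minus closed in the replicate 1 pair (x) and the replicate 2 pair (y). On the right, purple points give the SD of these differences over 4 libraries (0.888), the replicate 1 pair (1.60) and the replicate 2 pair (0.797), and grey squares with bars give the median and central 95% of 10000 matched random lists.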

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

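The tests of ribosomal RNA, of other cells and of genes of like abundance below were chosen after the result was seen, and the others before.

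A transcript row without a gene name, outside the comparisons, stood out: the ribosomal RNA transcript took 60.1% of reads in closed replicate 1 and at most 11.1% in the other libraries. Intestine-type transcripts also stood out, with 16 of 20 members that had not been looked at before highest in closed replicate 2.

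Receptor log2 ratios spread more widely in the replicate 1 pair (SD 1.60) than in the replicate 2 pair (SD 0.797). Closed replicate 2 was thinned to the depth of closed replicate 1, while open replicate 2, already shallower than open replicate 1, was kept whole. The replicate 2 pair then had 0.529 times the SD of the replicate 1 pair, and Poisson draws gave 0.21 times. This argues against fewer reads or counting error of independent reads alone. Both tests take reads as independent, so they do not cover counting error of molecules before amplification. Receptor genes spread 0.994 times as widely as other genes of like abundance in the replicate 1 pair, so a loss of detail in closed replicate 1 that met genes of any kind may account for the width. In that library 179 tested receptor genes had no read, against a mean of 21.4 in closed replicate 2 thinned to its depth. A difference in occlusion, sex or animals between the pairs stays open and was not tested.

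The mitochondrially encoded transcripts were lower on the open side in both pairs. Without the ribosomal RNA-rich library closed replicate 1 their median was -1.61, which argues against that library as the only origin. The closed library then left was closed replicate 2, which held intestine-type transcripts. Whether that RNA adds to the mitochondrial reads there was not tested. Of 11 lists of other cells, 0 had a median below -0.5 in both pairs (stroma came lowest, with -0.27 as the higher of its pair medians), but lymphocyte and red blood cell genes stood at -2.06 and -2.02 in the replicate 1 pair and gland genes at -1.17 in the replicate 2 pair, so carry-over of different unlabelled cells in each library stays open. RNA outside ribosomes also stays open, because nuclear non-coding RNAs went both ways: their medians were -0.21 and 0.00 in the replicate 1 and 2 pairs, with Malat1 at -1.74 and 0.06 and Neat1 at 0.83 and -0.44. Whole mitochondria carried through the precipitation, the left and right sides, and an effect of occlusion on the neurons were not tested, so that occlusion may be 1 of several candidates. Whether the mitochondrially encoded RNA was bound to the tagged ribosomes at all was not tested either.

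Intestine-type transcripts appeared in closed replicate 2, where Fabp1, Apoa4 and Reg3b had 135, 133 and 275 reads against 0 in each other library. Of 20 list members not seen before, 16 were highest there, which a share of RNA from intestinal tissue or another library could give. The exceptions Muc2, Fcgbp, Mttp and Slc5a1 also had reads in each other library, with Muc2 at 891 in open replicate 1. Occlusion as the origin needs closed replicate 1 to follow, and there 4 of 20 lay above both open libraries. That count cannot decide on occlusion, because closed replicate 1 had no read for 2298 of 20968 tested genes. Among them were Rrm2 and Lgr5, which had 284 and 183 reads in closed replicate 2. The origin of the RNA was not tested further.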

How the results depend on the processing

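The pseudocount of 1 and the summed rows were planned for the main test and became alternatives after the file was read. Library quality weights, limma-voom, single pairs and thinned reads were chosen after the data were seen. The count of genes past adjusted p 0.05, 0 in the test of side alone, was 4 without a filter, 18 with the replicate block, 21 with the block and rescaling by trimmed means, 3 with library quality weights, 9 with limma-voom and 39 with limma-voom and the block. It ranged from 2 to 265 with 1 library left out (265 without closed replicate 2), and was 0 under the other pseudocounts, the stricter filter, both rescalings, limma without trend, summed rows and single rows. For receptor genes it was 0 throughout except from 0 to 11 with 1 library left out, or 0 to 48 adjusted over the list alone. Lists past camera numbered 2, against 0 with an estimated correlation, 1 with a pseudocount of 0.5, 1 with a pseudocount of 5, 1 with a mean of at least 50, and 1 to 14 with 1 library left out, and lists with a median above 0 numbered 13, against 10 to 18 under other settings and 11 to 22 with 1 library left out. The block changed no other list or receptor call. The receptor SD over that of matched genes was 1.01, against 0.9995 with a pseudocount of 5 and 1.03 without a filter. It was 0.994 in the replicate 1 pair alone, 1.05 in the replicate 2 pair alone, and 0.926 to 1.08 with 1 library left out. Without closed replicate 1 the medians of horizontal basal cell genes and of atypical neuron genes turned to -0.27 and -0.57 and passed camera, within ranges of -0.27 to 0.85 and -0.57 to 1.12 with 1 library left out. The Pearson r of the pairs over receptor genes ranged from -0.0285 to 0.0332, and the difference in receptor share from 0.00127 to 0.0347 percentage points with 1 library left out, against -0.00729 over protein-coding reads. Over 78 named genes, 1006 of 1087 values under other settings and 261 of 312 with 1 library left out kept their sign and side of the threshold, 73 and 30 passed the threshold with the same sign, and 8 and 21 changed sign without passing. Of 315 list medians under other settings 287 were alike, 5 lost their call and 23 changed sign without passing, and with 1 library left out the numbers were 72, 2 and 50 of 140, with 14 newly past with the same sign and 2 with the opposite sign. The cause was not tested. edgeR and DESeq2 on recovered reads, and edgeR with the block, were not run. Low read numbers limit closed replicate 1 most, where a tested receptor gene had a median of 6 reads against 54 or 55 elsewhere. Closed replicate 2 thinned to its depth had a mean of 21.4 receptor genes without a read, against 179. With reads taken as independent, depth alone therefore does not account for the receptor genes without a read.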

Other observations

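The values by replicate number were read after the data were seen for lists picked by those values, and no test was run on them.

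Replicate numbers are also the sexes here. Of 21 proliferation genes, 16 were lower in replicate 1 than in replicate 2 on both the open and the closed side and 0 were higher on both, with median log2 differences of -0.84 and -0.96. Progenitor genes gave 12 of 15 lower on both sides, with medians of -1.13 and -0.87. Interferon-stimulated genes gave 12 of 14, with -1.35 and -1.40, and immature neuron genes 13 of 22, with -0.71 on each side. Of 14 presynaptic genes, 7 were higher in replicate 1 on both sides and 0 were lower, and of 16 stroma genes 10 were higher and 0 lower. Odorant receptor genes were lower in replicate 1 on both sides for 288 of 673 and higher on both for 86, but in closed replicate 1, the library rich in ribosomal RNA, 179 tested receptor genes had no read, against 7 in closed replicate 2.

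Cabs1 had 6143 reads in closed replicate 2 and 7, 5 and 3 in open replicate 1, open replicate 2 and closed replicate 1. Bpifb9a had 405722 reads in closed replicate 2 and 3522 in closed replicate 1, against 1600 and 1960 in the open libraries. Malat1, a nuclear RNA, had a log2 value of 18.68 in closed replicate 1 and 16.94, 17.70 and 17.65 in open replicate 1, open replicate 2 and closed replicate 2.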
